A study of Mus musculus with 20 samples.

How the data were processed

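Liver RNA of 20 mice in 5 groups of 4 is described in the labels. The table held 1 column per library, and the 4 columns of the white tea extract group held no value in any row, so that group was not analysed here. The design written before the data were examined took all 20 libraries and 5 groups in a single fit, and the fit therefore used 16 libraries and 4 groups. Groups came from the labels alone. Total RNA was extracted with TRIzol and treated with DNase, and sequencing libraries followed standard Illumina protocols, per the labels. The sex of the mice and the strain background of the db/db animals were not given in the sources used here.

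The deposited values are whole-number read counts per Ensembl gene, not normalized, and their column totals differ between libraries. The submitters' processing notes name CASAVA 1.8.2, FastQC 0.11.5, HISAT2 2.1.0, StringTie 1.3.3b, DESeq2 1.28.0 and the genome build GRCm38, without saying what each did or in which order. The annotation, the strand setting and the treatment of reads that match several genes were not given in the sources used here. Counts of near-identical gene copies, overlapping genes and antisense partners are therefore uncertain. The table held 46078 genes. Symbols and coordinates came from GENCODE M21 (Ensembl 96, GRCm38), which matched 45143 of them (98%), and the unmatched genes held 0.064% of reads. A symbol was shared with a more abundant identifier by 163 identifiers, for which the more abundant one was used.

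Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, and figures were drawn with Python 3.11.15. Genes were filtered with filterByExpr, which left 15744, libraries were scaled by TMM, and a quasi-likelihood model with robust dispersions (glmQLFit and glmQLFTest) was fitted to all groups together. Every p-value of a gene is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested unless another tool is named, and a gene was called at an adjusted p under 0.05. The tests are two-sided. Levels are CPM after TMM scaling, and plots and list means use log2(CPM + 0.5). A fold against a group with no read was computed against a floor of 3 counts over the group and is a lower bound. Ratios of groups with 1 to 3 reads carry an exact 95% counting interval.

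For gene groups, 37 lists with 867 entries (860 found in the table) were fixed before the data were examined, and the 36 with at least 5 members tested entered camera with a preset correlation of 0.01, adjusted over the lists of a comparison. The median correlation estimated from the data was 0.42, 0.4, 0.41 and 0.4 in model versus normal, PGZ versus model, DLE versus model and DLE versus PGZ, far above the preset value, so camera's preset p-values are too small where the members of a list vary together. For that reason p-values with the estimated correlation stand beside them. Over the lists of a comparison 17, 16, 16 and 18 were called with the preset and 1, 2, 0 and 0 with the estimated correlation.

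Named genes followed a rule fixed before the data were examined. Up to 8 higher and 8 lower genes (3 and 3 between treatments) with the largest fold change were taken among called genes with a CPM of at least 1 and no overlap between groups. Up to 3 called members per list with the smallest p, or the 2 with the smallest p where a list was called with no such member, were added. Further parts took Lepr in every comparison, Pparg with PGZ, the 5 genes with the smallest p where fewer than 5 were called, and up to 6 genes per treatment moved back towards normal. List members could be left out of the text, and some genes chosen in these ways are not reported here. Of 96 called genes named in model versus normal, 49 were called with any 1 library left out. Chosen after their values were seen were Saa1, Saa2, Mpo, Cyp7a1 and Nnt in model versus normal, and the levels of S100a8 and Hyou1 in single model libraries. So were Cidea, Cidec, Scd1, Mogat1, Fasn and Slco1a1 with PGZ, Slco1a1 and Cidea with DLE, Cidea, Cidec and Fabp4 in DLE versus PGZ, and the genes of the major histocompatibility region.

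Alternatives fixed beforehand were other scalings (RLE, upper quartile), no filter and a stricter filter (at least 1 CPM in 4 libraries and 200 reads), a fit of only the groups compared, a fold of at least 1.5 tested with glmTreat, DESeq2 1.42.0, limma voom with quality weights, the estimated correlation, fry, and each library left out in turn. Leaving out model_327 and model_387, and leaving out these with model_PGZ_328 and model_DLE_361, were added after the data were seen. Because both treatments were compared with the same model libraries, unchanged treatment groups were simulated 50 times, and the model libraries were also divided between contrasts in all 6 ways. The simulations drew each gene independently of the others.

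The procedure was tested on counts simulated for 15744 genes, of which 200 were changed. Each gene was drawn independently, with edgeR's own dispersions, alike in all groups. In model versus normal edgeR called 24% of genes changed 2-fold and 78% of those changed 4-fold, and 3.8% of its calls were false. The shares were 19% and 79% with 2% false in PGZ versus model, 27% and 77% with 7.1% false in DLE versus model, and 20% and 79% with 3.9% false in DLE versus PGZ. DESeq2 called 36% and 89% with 21% false in model versus normal and 42% and 90% with 15% false in PGZ versus model. Voom with quality weights called 23% and 77% with 3.8% false and 20% and 75% with 2% false in the same comparisons. Camera found the simulated list of 25 raised genes in each of the 4 comparisons, and of the 4 lists of unchanged genes 1 fell under 0.05 (0.026 in model versus normal). A known covariance of 0.254 between treatments was found as 0.252.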

Results

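Liver RNA was sequenced in 16 libraries of 4 groups, with 4 libraries per group. The normal group held wild-type C57BL/6J mice given saline. The remaining groups held db/db mice, which carry a mutation of the leptin receptor gene Lepr and become obese and diabetic. These received saline (model), pioglitazone at 20 mg/kg (PGZ), a drug that activates the nuclear receptor PPAR-gamma, or an extract of leaves of the bamboo Dendrocalamus latiflorus at 200 mg/kg (DLE). Treatment lasted 12 weeks. Libraries are named as in their labels (such as model_327 or model_PGZ_328), which do not say whether animals shared a cage, a day or a batch. The p-values therefore measure the spread between these libraries. The 4 libraries of a group given white tea extract were not analysed here.

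Total counts ranged from 16922833 to 21622959 per library in the normal group, from 17993327 to 25119799 in the model group, from 19332589 to 22415530 with PGZ and from 18300173 to 24105179 with DLE (n = 4 each). All levels below are CPM values (read counts relative to the library total after TMM scaling), as mean ± SD over 4 libraries. A total of 3 reads over a group corresponded to 0.041 CPM in the normal and 0.035 CPM in the model group. Such floors and all counting intervals cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules. Correlations of log2 CPM between libraries of a group, computed across genes, were 0.959 to 0.987 in normal, 0.877 to 0.975 in model, 0.958 to 0.985 in PGZ and 0.946 to 0.972 in DLE libraries. No pair of libraries of a group matched within sampling noise.

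Lepr RNA (chromosome 4, 101717404 to 101815352, GRCm38) was read in every library. It averaged 1.75 ± 0.316 CPM in normal, 5.63 ± 1.87 in model, 5.33 ± 1.71 in PGZ and 11.5 ± 6.89 in DLE libraries. The model level was higher than the normal one (log2 fold change 1.68, SE 0.43, adjusted p = 0.026), and the treated groups were not called different from the model group (adjusted p = 0.96 in PGZ and 0.28 in DLE). The call in model versus normal was lost without any 1 of the 4 normal libraries (adjusted p = 0.058 to 0.072) and without model_327 (adjusted p = 0.055). Gene counts sum all transcripts of Lepr, so this level does not check the genotype.

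Libraries of the model group differed widely in acute-phase RNA. Saa1, which encodes the serum amyloid A protein that liver secretes in inflammation, stood at 27800 CPM in model_327, 10200 in model_387, 1360 in model_407 and 94.9 in model_329. It reached 4570 CPM in model_PGZ_328 and 1970 in model_DLE_361, against 73.5 to 279 in the other PGZ and 54.9 to 221 in the other DLE libraries, and 23.2 to 131 in normal libraries. model_387 also held 244 CPM of Mpo, a neutrophil granule gene, and 464 CPM of S100a8, and model_327 held 627 CPM of the endoplasmic reticulum chaperone gene Hyou1. The first principal component held 30.5% of the variance and placed the normal libraries at -83.5 to -64.5 and the model libraries at -24.2 (model_329), 15.7 (model_407), 79.6 (model_387) and 87.1 (model_327).

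**Figure D1:**
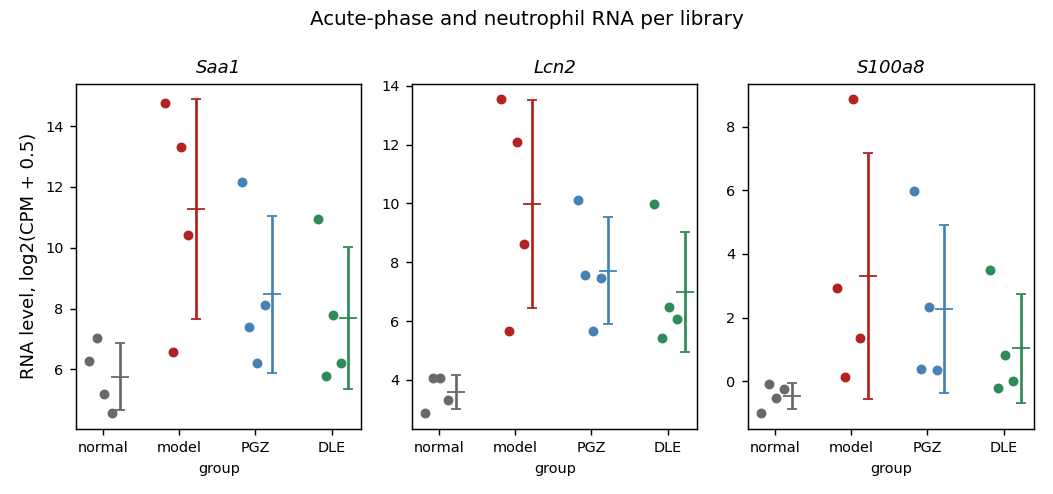
Saa1, Lcn2 and S100a8 RNA in each of the 16 libraries, as log2(CPM + 0.5) on the vertical axis, with libraries as points by group and the mean ± SD of 4 libraries as bars. model_327 (27800 CPM of Saa1) and model_387 (10200 CPM) lie above all other libraries for Saa1 and Lcn2, and S100a8 is highest in model_387 (464 CPM).

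The comparison of model with normal libraries asked how the diabetic db/db liver differed from wild-type liver. Male-biased liver genes, those with more RNA in male than in female mouse liver, were the list with the smallest p and fell. Selenbp2, a selenium-binding protein gene expressed above all in male liver (chromosome 3, 94693556 to 94704413), fell from 4110 ± 192 CPM in normal to 3.65 ± 1.17 CPM in model libraries (log2 fold change -10.13, SE 0.54, adjusted p = 2.5e-08, n = 4 each). Cyp7b1, the oxysterol hydroxylase of the alternative bile acid pathway (chromosome 3, 18071950 to 18243338), fell from 303 ± 123 to 9.28 ± 4.61 CPM (log2 fold change -5.03, SE 0.44, adjusted p = 1.2e-05). Hsd3b5, a steroid-metabolising dehydrogenase gene, averaged 209 ± 83.2 CPM in normal libraries and 0.161 ± 0.206 CPM in model libraries (adjusted p = 2.5e-05). Of 21 male-biased liver genes tested, 17 fell, 0 rose and 4 were not called, and 20 fell when adjusted over the list alone. The list fell as a whole (median log2 fold change -3.33, camera adjusted p = 2.8e-39), and adjusted p was 0.00045 with an estimated correlation, the only list of this comparison called that way. Of 26 female-biased liver genes, 16 rose, 1 fell and 9 were not called, with 20 rising and 1 falling when adjusted over the list alone (median 4.74, or 4.13 with 8 genes absent from the normal group set at their floor, camera adjusted p = 3e-11). With an estimated correlation the female-biased list had an adjusted p = 0.36. Its mean log2 CPM was 5.37 in model_329, 3.61 in model_407, 2.12 in model_327 and 1.94 in model_387, against 0.68 to 0.89 in normal libraries. Its members Cyp17a1, which makes androgen precursors, and the cytochrome gene Cyp2b9 rose from 3.45 ± 2.63 to 78.8 ± 38.8 CPM (log2 fold change 4.50, SE 0.57, adjusted p = 0.00032) and from 0.286 ± 0.406 to 188 ± 217 CPM (adjusted p = 0.00067, log2 fold change 9.24, or 8.19 without model_329 and 10.86 without normal_376). The member that fell was Lifr, a receptor for leukaemia inhibitory factor (log2 fold change -3.02, SE 0.34, adjusted p = 9.8e-05). Every library of both groups held the Y-linked RNA Ddx3y (794 to 1394 reads) and few reads of Xist (0 to 19).

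**Figure D2:**
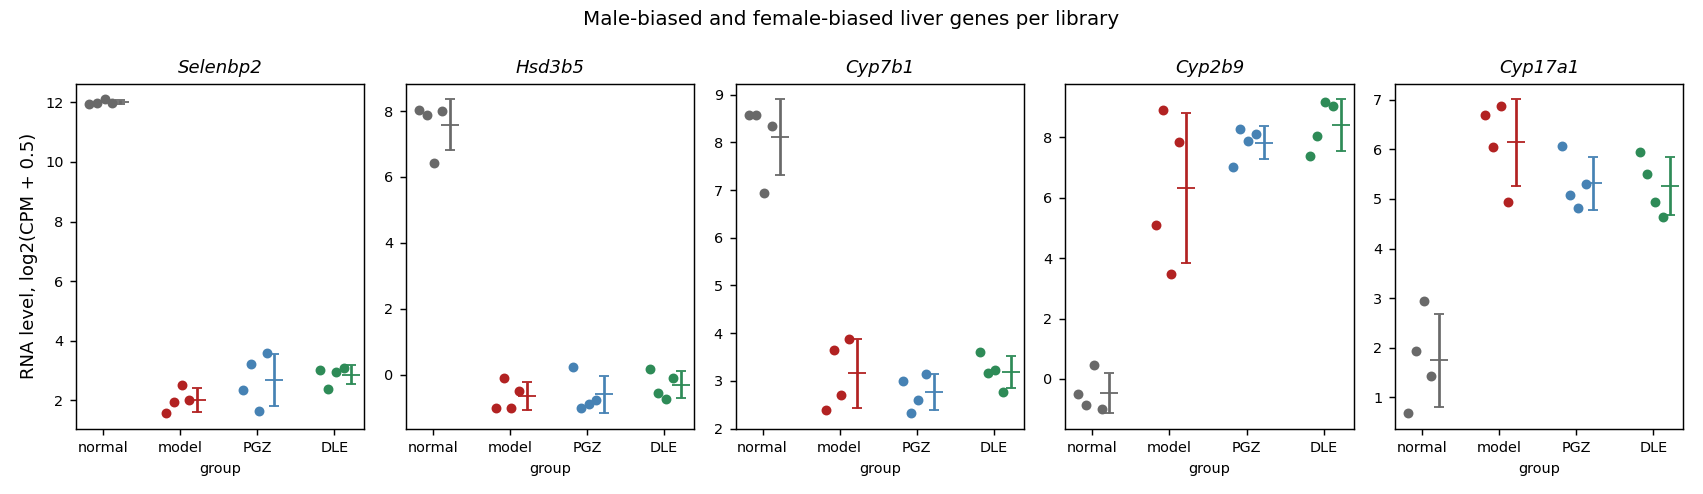
Male-biased (Selenbp2, Hsd3b5, Cyp7b1) and female-biased (Cyp2b9, Cyp17a1) liver genes in each library, as log2(CPM + 0.5) on the vertical axis, with libraries as points by group and the mean ± SD of 4 libraries as bars. Selenbp2 averages 4110 CPM in normal and 3.65 CPM in model libraries, and Cyp17a1 averages 3.45 CPM in normal and 78.8 CPM in model libraries.

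Several of the genes with the largest differences had no read in one of the groups. Sult3a1, a sulfotransferase gene, was absent from the normal group and at least 1650-fold higher in the model group (67.8 ± 103 CPM). The sulfotransferase gene Sult2a2 was at least 337-fold higher, the cytochrome genes Cyp2b13 and Cyp3a41b at least 3070-fold and 502-fold, the chitinase-like genes Chil3 and Chil1 at least 1270-fold and 771-fold, and the plasma glycoprotein gene A1bg at least 273-fold. The calls of Sult3a1 and A1bg held in every fit with 1 library left out. Those of Cyp2b13 (adjusted p = 0.058 to 0.066), Chil3 (0.068 to 0.077) and Sult2a2 (0.078 to 0.087) were lost without any 1 of the 4 normal libraries. Chil3 and Chil1 were also lost without model_327 (adjusted p = 0.053 and 0.051), Sult2a2 without model_329 (0.053) and Cyp3a41b without normal_409 (0.052). Single libraries carried much of some bounds, which were at least 42.9-fold for Chil3 without model_387 (202 CPM there, 0.0538 to 4.04 in the other model libraries) and 11.5-fold for Sult2a2 without model_329 (53.7 CPM there, 0.195 to 0.978 in the others). Without the library that lowered it most, the bound was 726-fold for Cyp2b13, 406-fold for Sult3a1, 135-fold for Cyp3a41b, 501-fold for Chil1 and 126-fold for A1bg. Serpina9, a serine protease inhibitor gene, was at least 193-fold lower in the model group, where it had no read. The major urinary protein genes Mup7 and Mup6, which encode pheromone carriers, fell from 7630 ± 5060 to 10.3 ± 9 CPM and from 43.4 ± 40.7 to 0.355 ± 0.145 CPM (adjusted p = 0.0021 and 0.00089). The related pseudogene Mup-ps7 had 506 reads in normal and 2 in model libraries, a ratio of 303 (95% exact counting interval 83.4 to 2510). Serpina4-ps1 fell from 1060 ± 436 to 1.88 ± 1.4 CPM and the monooxygenase gene Moxd1 from 140 ± 57.3 to 0.321 ± 0.642 CPM (adjusted p = 0.00075 and 0.015). Members of the Mup, Cyp2b, Cyp3a, Sult and Hsd3b families share sequence, so the assignment of reads among near-identical copies is uncertain.

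Genes of lipid uptake and storage were higher in model libraries. Cd36, a fatty acid transporter (chromosome 5, 17781690 to 17888801), rose from 5.3 ± 3.6 to 144 ± 76.8 CPM (log2 fold change 4.76, SE 0.50, adjusted p = 5.9e-05). Pparg, which encodes the receptor that pioglitazone binds, rose from 5.67 ± 1.07 to 15.1 ± 2.89 CPM (log2 fold change 1.41, SE 0.25, adjusted p = 0.0041), and Mogat2, a monoacylglycerol acyltransferase gene, rose with a log2 fold change of 4.40 (SE 0.62, adjusted p = 0.00068). Of 22 genes of the PPAR-gamma and lipid droplet list, 7 rose and 15 were not called, with 9 rising when adjusted over the list alone (camera adjusted p = 4.1e-05, adjusted p = 0.41 with an estimated correlation). Of 35 genes of PPAR-alpha and fatty acid oxidation, 8 rose and 27 were not called, with 10 rising when adjusted over the list alone (camera adjusted p = 0.0016, adjusted p = 0.62 with an estimated correlation). That list lost its call without model_329 (adjusted p = 0.064). The fatty acid hydroxylase genes Cyp4a14 and Cyp4a10 were among them, at 451 ± 389 against 4.23 ± 3.85 CPM and 593 ± 580 against 49.2 ± 12.2 CPM (adjusted p = 0.00096 and 0.0062), though this pair also shares sequence. Vnn1, a pantetheinase gene, rose with a log2 fold change of 3.51 (SE 0.57, adjusted p = 0.0021).

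Sugar, bile acid and redox genes differed as well. Of 24 genes of glycolysis and fructose use, 7 rose and 17 were not called, with 12 rising and 2 falling when adjusted over the list alone (camera adjusted p = 0.002, adjusted p = 0.36 with an estimated correlation). Pkm, a pyruvate kinase gene, rose from 8.55 ± 2.31 to 60.6 ± 69.2 CPM (adjusted p = 0.0096), with 163 CPM in model_387 and 13.3 to 38 in the other model libraries. Without model_387 its log2 fold change moved from 2.82 to 1.63 (adjusted p = 0.011). The gluconeogenesis list was not called (camera adjusted p = 0.24), and of its 17 genes 1 rose and 16 were not called, namely Fbp1, which rose from 154 ± 37.5 to 533 ± 274 CPM (adjusted p = 0.0049). Among 22 genes of bile acid synthesis and transport, 4 fell, 2 rose and 16 were not called, with 5 falling and 2 rising when adjusted over the list alone (camera adjusted p = 0.00015, adjusted p = 0.43 with an estimated correlation). The organic anion transporter gene Slco1a1 fell from 305 ± 45.8 to 10.1 ± 9.67 CPM (log2 fold change -4.92, SE 0.77, adjusted p = 0.0018), while the exporter gene Abcc4 rose from 0.702 ± 0.355 to 5.46 ± 2.43 CPM (adjusted p = 0.0051). Of 25 antioxidant genes and NRF2 targets, 9 rose, 1 fell and 15 were not called, with 12 rising and 1 falling when adjusted over the list alone (camera adjusted p = 0.00023, adjusted p = 0.41 with an estimated correlation). The quinone reductase gene Nqo1 rose with a log2 fold change of 1.85 (SE 0.31, adjusted p = 0.0027), and Osgin1, an oxidative stress-induced growth inhibitor gene, fell with one of -2.36 (SE 0.35, adjusted p = 0.00094). Outside that list, the glutathione transferase gene Gstp1 fell from 991 ± 418 to 192 ± 57.1 CPM (adjusted p = 0.0013). In the lipoprotein list, which was not called (camera adjusted p = 0.67), 5 of 24 genes rose, 1 fell and 18 were not called, with 6 rising and 1 falling when adjusted over the list alone. Apoa4 and the receptor gene Vldlr rose (adjusted p = 0.0055 and 0.012), and Apoa1 fell (adjusted p = 0.047), a call lost in 7 of the 8 fits with 1 library left out. The log2 fold change of Apoa4 moved from 4.76 to 3.09 without model_327, and that of Vldlr from 4.84 to 3.76 without model_329.

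Inflammatory and macrophage genes were higher in model libraries. Of 25 acute-phase protein genes, 11 rose and 14 were not called, with 20 rising when adjusted over the list alone (median log2 fold change 2.47, camera adjusted p = 1.3e-06, adjusted p = 0.61 with an estimated correlation). Lcn2, an iron-carrier binding protein gene, stood at 11900 CPM in model_327, 4370 in model_387, 392 in model_407 and 49.9 in model_329, against 12.2 ± 4.7 CPM in normal libraries (adjusted p = 0.011). Of 26 cytokine and chemokine genes, 10 rose and 16 were not called, with 20 rising when adjusted over the list alone (camera adjusted p = 1e-05, adjusted p = 0.54 with an estimated correlation). The mean log2 CPM of the acute-phase list was 11.86 in model_327, 10.76 in model_387, 8.65 in model_407 and 7.49 in model_329, against 7.20 to 7.69 in normal libraries. Kupffer cell markers, those of the resident liver macrophages, rose for 9 of 14 genes, with 5 not called and 10 rising when adjusted over the list alone (camera adjusted p = 9.7e-06, adjusted p = 0.43 with an estimated correlation). Their mean log2 CPM was 6.15 in model_387, 5.01 in model_407, 3.49 in model_329 and 3.47 in model_327, against 2.23 to 3.18 in normal libraries, an order that differed from that of Saa1. Markers of lipid-associated and recruited macrophages rose for 11 of 15 genes, with 4 not called and 12 rising when adjusted over the list alone (camera adjusted p = 1.2e-07, adjusted p = 0.36 with an estimated correlation). Lgals3, a galectin gene of macrophages, averaged 36.1 ± 45.7 CPM against 1.78 ± 0.554 CPM, and the complement gene C1qa averaged 77 ± 80.4 against 10.9 ± 4.44 CPM (adjusted p = 0.0053 and 0.0096). The library model_387 held 104 CPM of Lgals3 and 194 of C1qa, and without it their log2 fold changes moved from 4.33 to 2.89 and from 2.81 to 1.79 (adjusted p = 0.0062 and 0.015). Of 11 neutrophil markers 6 rose and 5 were not called, with 11 rising when adjusted over the list alone (camera adjusted p = 0.0041, adjusted p = 0.62 with an estimated correlation), and their mean log2 CPM was 6.70 in model_387 and -0.25 to 1.16 in the other model libraries. Cell cycle genes rose for 3 of 28 genes, with 25 not called and 8 rising when adjusted over the list alone (camera adjusted p = 0.0023, adjusted p = 0.62 with an estimated correlation), and lost the list call without model_387 (adjusted p = 0.23). Without model_327 and model_387 together, 9 of the 17 lists called in this comparison remained so, the Kupffer cell (adjusted p = 1.3e-08) and recruited macrophage markers (4.2e-06) among them. The acute-phase (median 0.37, adjusted p = 0.19), cytokine (0.59, 0.14), neutrophil (2.11, 0.064) and cell cycle lists (0.31, 0.12) were then not called, nor were the bile acid (adjusted p = 0.067), ribosomal (0.62), mitochondrial (0.11) and periportal lists (0.4).

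The other lists called in this comparison had few called members. Erythroid markers had 0 of 7 members called and 4 rising when adjusted over the list alone (camera adjusted p = 0.028, adjusted p = 0.62 with an estimated correlation), a list call lost without normal_376 (adjusted p = 0.062) or model_329 (0.24). Cytosolic ribosomal protein genes had 1 of 75 members called higher and 0 when adjusted over the list alone (camera adjusted p = 0.0061, adjusted p = 0.79 with an estimated correlation), a list call lost without normal_376 (adjusted p = 0.4), model_327 (0.18) or model_387 (0.052). Mitochondrially encoded genes had 0 of 13 members called and 0 when adjusted over the list alone, with a lower list mean (median -0.66, camera adjusted p = 0.0024, adjusted p = 0.62 with an estimated correlation). The share of all counts from the mitochondrial genome was 19.6 ± 2.05% in normal and 15.4 ± 4.3% in model libraries, where model_327 had 9.71%. Periportal hepatocyte genes fell for 3 of 16 genes, with 13 not called and 4 falling and 1 rising when adjusted over the list alone (camera adjusted p = 0.028, adjusted p = 0.49 with an estimated correlation), a list call lost without normal_409 (adjusted p = 0.079) or model_327 (0.17). The remaining 19 of the 36 lists, which included cholesterol synthesis, insulin signalling, interferon-stimulated genes, extracellular matrix genes and T, B and endothelial cell markers, were not called.

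In all, 1429 of 15744 genes tested passed an adjusted p of 0.05 in model versus normal (973 higher and 456 lower), and 1156 of them differed at least 2-fold. The groups did not overlap for 13.7% of genes tested, against 2.86% by chance. The count of 1429 was 632 without normal_346, 644 without normal_349, 720 without normal_376, 505 without normal_409, 2909 without model_329 and 803 without model_387. It was 226 when only these groups were fitted (110 higher and 116 lower), 2440 with DESeq2 (1595 and 845) and 4287 with limma's quality weights (2243 and 2044).

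The comparison of PGZ with model libraries asked what pioglitazone changed in the db/db liver. Sdcbp2, a syntenin family adaptor gene (chromosome 2, 151572622 to 151590005), rose from 0.375 ± 0.141 CPM in model to 27.5 ± 11.1 CPM in PGZ libraries (log2 fold change 6.18, SE 0.66, adjusted p = 0.00078, n = 4 each). Abcd2, a peroxisomal transporter of fatty acids (chromosome 15, 91145871 to 91191799), rose from 2.74 ± 1.14 to 17.9 ± 5.95 CPM (log2 fold change 2.70, SE 0.41, adjusted p = 0.04). These were the only genes that passed by edgeR, of 1539 with an unadjusted p under 0.05 (641 higher and 898 lower), and for both all 4 PGZ libraries lay above all 4 model libraries. Abcd2 belongs to the female-biased list. Sdcbp2 was called in each of 9 other settings (adjusted p = 4.5e-23 to 0.017), and Abcd2 in 7 of 9 (adjusted p = 4.8e-07 to 0.19). Abcd2 lost its call without model_327 (adjusted p = 0.055), model_387 (0.078), model_407 (0.089), model_PGZ_360 (0.15), model_PGZ_404 (0.22) or model_PGZ_408 (0.17). DESeq2 called 135 genes (82 higher and 53 lower) and limma's quality weights 1598 (760 and 838). The count of 2 was 1 without model_327, model_PGZ_360, model_PGZ_404 or model_PGZ_408, 4 without model_329 and 5 without model_407. It was 216 (64 higher and 152 lower) without model_327, model_387, model_PGZ_328 and model_DLE_361 together, an exclusion chosen after the data were seen. The groups did not overlap for 4.88% of genes, against 2.86% by chance.

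Lipid synthesis and storage lists rose with PGZ although 0 of their members passed over all genes by edgeR. De novo lipogenesis genes had 22 of 25 positive fold changes, and 9 rose and 0 fell when adjusted over the list alone (median 0.84, camera adjusted p = 3.9e-16, adjusted p = 0.0093 with an estimated correlation). Acaca, which encodes acetyl-CoA carboxylase, averaged 126 ± 17.8 CPM against 59.2 ± 7.14 CPM (adjusted p = 0.12), and Fasn, the fatty acid synthase gene, 755 ± 117 against 268 ± 36.9 CPM (adjusted p = 0.14). Thrsp, a gene of lipogenesis, averaged 1010 ± 103 against 237 ± 176 CPM (adjusted p = 0.12), and 0.033 without model_407. Adipocyte markers had 2 of 7 members rising when adjusted over the list alone (median 1.24, camera adjusted p = 0.00013, adjusted p = 0.03 with an estimated correlation). The fatty acid-binding protein gene Fabp4 averaged 93 ± 36.6 CPM against 15.9 ± 4.58 CPM (adjusted p = 0.15), and Cfd, which encodes adipsin, 34.9 ± 18.2 against 0.848 ± 1.09 CPM (adjusted p = 0.37). The PPAR-gamma and lipid droplet list had 8 of 22 members rising when adjusted over the list alone (median 0.79, camera adjusted p = 1.9e-13, adjusted p = 0.066 with an estimated correlation). Its lipid droplet coat gene Plin4 averaged 241 ± 112 against 37 ± 19.6 CPM and the lipase gene Pnpla2 142 ± 20.5 against 87.2 ± 11.8 CPM (adjusted p = 0.14 and 0.15). The lipid droplet genes Cidea and Cidec averaged 110 ± 36.7 against 13.2 ± 20.1 CPM and 184 ± 79.1 against 32.5 ± 55.5 CPM (adjusted p = 0.46 for both). The library model_327 held 42.5 CPM of Cidea and 116 of Cidec, against at most 9.74 and 9.65 in the other model libraries. Without it their log2 fold changes moved from 3.06 to 5.01 and from 2.51 to 5.27 (adjusted p = 0.26 and 0.055). Pparg itself averaged 20.3 ± 2.77 against 15.1 ± 2.89 CPM (adjusted p = 0.58).

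**Figure D3:**
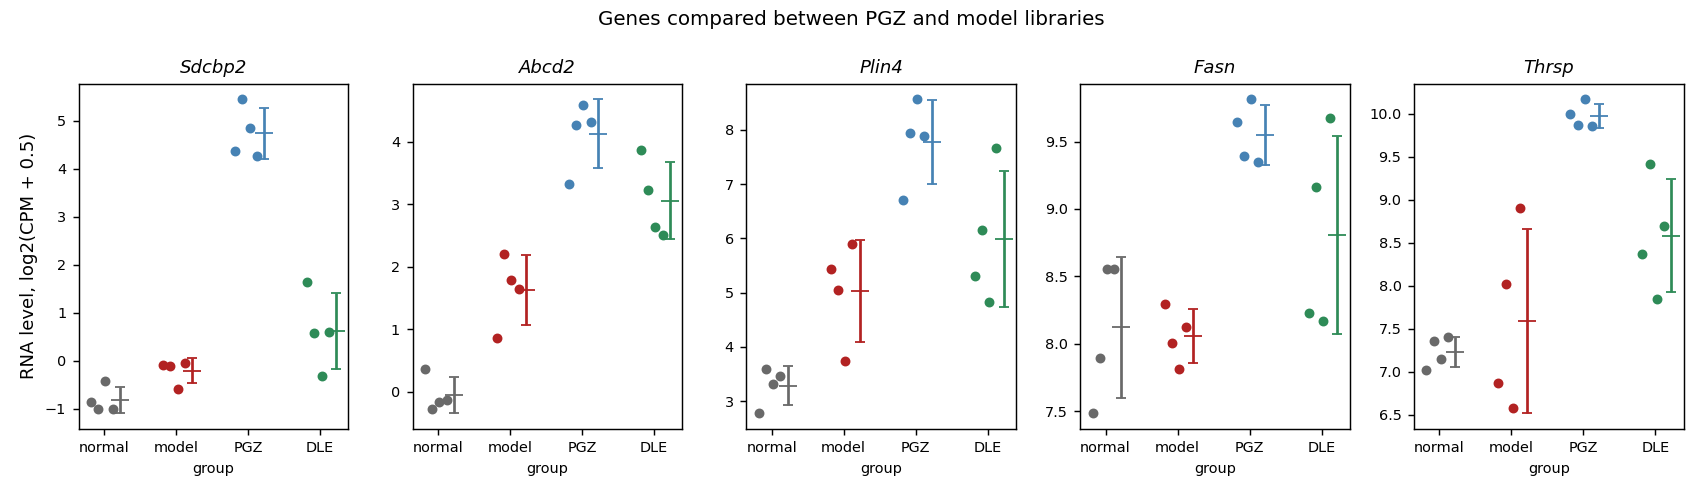
Sdcbp2, Abcd2, Plin4, Fasn and Thrsp RNA in each library, as log2(CPM + 0.5) on the vertical axis, with libraries as points by group and the mean ± SD of 4 libraries as bars. Sdcbp2 averages 27.5 CPM in PGZ libraries against 0.375 CPM in model and 1.22 CPM in DLE libraries.

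Fatty acid oxidation genes rose as a list in PGZ versus model (30 of 35 with a positive fold change, 5 rising when adjusted over the list alone, camera adjusted p = 1.4e-11, adjusted p = 0.45 with an estimated correlation). The acyl-CoA thioesterase gene Acot2 averaged 36 ± 13.2 CPM against 9.58 ± 3.7 CPM and the peroxisome gene Pex11a 307 ± 115 against 118 ± 34.5 CPM (adjusted p = 0.12 and 0.24). Extracellular matrix and stellate cell genes rose as a list (24 of 28 with a positive fold change, 0 called over the list alone, camera adjusted p = 3.4e-09, adjusted p = 0.5 with an estimated correlation), as did sinusoidal endothelial markers (14 of 14 positive, 0 over the list alone, camera adjusted p = 1.2e-05, adjusted p = 0.5 with an estimated correlation). Oxidative phosphorylation genes had 70 of 76 positive fold changes and 0 called over the list alone (median 0.15, camera adjusted p = 0.00041, adjusted p = 0.91 with an estimated correlation), and lost the call without model_387 (adjusted p = 0.32). Pericentral hepatocyte genes fell as a list (median -0.51, 0 called over the list alone, camera adjusted p = 0.0048, adjusted p = 0.64 with an estimated correlation), a call lost without model_329 (adjusted p = 0.18) or model_407 (0.33). The lists of cholesterol synthesis (camera adjusted p = 0.045), glycolysis and fructose use (0.026) and xenobiotic metabolism (0.045) were called higher with medians of 0.11, -0.01 and -0.01, so that the last 2 medians and the test differed in sign. Their adjusted p was 0.9, 0.5 and 0.86 with an estimated correlation, and 2, 2 and 1 members rose when adjusted over the list alone. Cholesterol synthesis lost its call without model_PGZ_328 (adjusted p = 0.72), model_329 (0.23), model_387 (0.34) or model_407 (0.29). Glycolysis lost it without model_PGZ_360 (0.072), model_329 (0.27) or model_407 (0.056), and xenobiotic metabolism without model_PGZ_360 (0.13), model_327 (0.81) or model_387 (0.91). Hk2, a hexokinase gene, averaged 39.2 ± 16.9 against 5.48 ± 7.26 CPM (adjusted p = 0.27, and 0.023 without model_387), and the glutathione transferase gene Mgst3 149 ± 61.3 against 24.5 ± 15.5 CPM (adjusted p = 0.12, and 0.049 without model_329). Without model_327 and model_387 together, 6 of the 10 lists called higher in PGZ remained so. Oxidative phosphorylation (adjusted p = 0.26), sinusoidal endothelial (0.16) and adipocyte markers (0.052) were not called, and xenobiotic metabolism was called lower (2.6e-05).

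Acute-phase, cytokine, interferon and stress lists were lower in PGZ than in model libraries, where model_327 and model_387 held the high acute-phase levels given above. Acute-phase protein genes fell as a list (24 of 25 with a negative fold change, 6 falling when adjusted over the list alone, camera adjusted p = 3e-10, adjusted p = 0.5 with an estimated correlation). Interferon-stimulated genes did so with 17 of 28 falling when adjusted over the list alone (camera adjusted p = 3.4e-12, adjusted p = 0.45 with an estimated correlation). Isg15, a ubiquitin-like gene of this list, averaged 5.33 ± 1.13 against 25.8 ± 25.1 CPM (adjusted p = 0.2). The endoplasmic reticulum stress list fell with 7 of 24 members over the list alone (camera adjusted p = 2.2e-06, adjusted p = 0.56 with an estimated correlation), a call lost without model_327 (adjusted p = 0.6). The cytokine and chemokine list fell with 1 of 26 over the list alone (camera adjusted p = 0.00058, adjusted p = 0.7 with an estimated correlation), a call lost without model_387 (adjusted p = 0.91). Lists of immune cells were not called, those of Kupffer cells and neutrophils (camera adjusted p = 0.31 for both), recruited macrophages (0.9, with the test higher), T and NK cells (0.58) and B cells (0.57). Erythroid markers fell with 0 of 7 over the list alone (camera adjusted p = 0.042, adjusted p = 0.7 with an estimated correlation), a call lost without model_329 (adjusted p = 0.43) or model_407 (0.17). Without model_327 and model_387 together, an exclusion chosen after the data were seen, the acute-phase list was not called (median 0.26, adjusted p = 0.45), nor were the interferon (-0.16, 0.25) and stress lists (0.14, 0.41). The cytokine list was then called higher (median 0.59, adjusted p = 0.01), and the erythroid list remained lower (-1.35, 4.4e-06).

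The comparison of DLE with model libraries asked what the bamboo leaf extract changed in the db/db liver. The genes with the smallest p were Pde4b, a cAMP phosphodiesterase gene (8.95 ± 1.8 CPM in DLE against 27.8 ± 13.7 CPM in model libraries), and Cdr2 (0.289 ± 0.242 against 3.65 ± 2.71 CPM). They were followed by 2900005J15Rik (9.75 ± 4.99 against 2.37 ± 1.2 CPM), Lingo4 (18.2 ± 13.2 against 4.26 ± 1.19 CPM) and Cdc42ep2 (1.71 ± 0.258 against 7.26 ± 6.24 CPM), all with an adjusted p = 0.21 and n = 4 each. With edgeR 0 genes passed, of 2249 with an unadjusted p under 0.05 (763 higher and 1486 lower), while DESeq2 called 386 (76 higher and 310 lower) and limma's quality weights 11 (8 higher and 3 lower). The groups did not overlap for 2.69% of genes, against 2.86% by chance. Without model_329, the model library with the lowest Saa1, 511 genes passed, among them Pde4b (adjusted p = 0.031) and Cdr2 (0.034). Without model_DLE_361 or without model_DLE_378 a single gene passed.

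Gene lists moved in DLE versus model with 0 members passing over all genes by edgeR. Fatty acid oxidation genes rose as a list (28 of 35 with a positive fold change, 1 rising when adjusted over the list alone, camera adjusted p = 2.2e-07, adjusted p = 0.44 with an estimated correlation). Ppara, which encodes the receptor that drives many of them, averaged 53.3 ± 20 CPM against 19.6 ± 10.4 CPM (adjusted p = 0.21, and 0.034 without model_329). De novo lipogenesis rose with 19 of 25 positive fold changes and 1 member over the list alone (camera adjusted p = 0.0019, adjusted p = 0.44 with an estimated correlation). Bile acid genes rose as a list (18 of 22 positive, 0 over the list alone, camera adjusted p = 0.00053, adjusted p = 0.44 with an estimated correlation), and the bile acid receptor gene Nr1h4 averaged 352 ± 51.2 against 229 ± 81.4 CPM (adjusted p = 0.34). Xenobiotic metabolism genes rose with 23 of 32 positive fold changes and 0 over the list alone (camera adjusted p = 0.00024, adjusted p = 0.45 with an estimated correlation), a call lost without model_387 (adjusted p = 0.09). The drug-sensing receptor gene Nr1i2 averaged 187 ± 48.7 against 83.8 ± 50.1 CPM (adjusted p = 0.21, and 0.035 without model_329). Circadian clock genes rose with 3 of 20 over the list alone (camera adjusted p = 0.0085, adjusted p = 0.44 with an estimated correlation), a call lost without model_387 (adjusted p = 0.14). Female-biased liver genes rose with 1 of 26 over the list alone (camera adjusted p = 0.014, adjusted p = 0.58 with an estimated correlation), a call lost without model_327 (adjusted p = 0.12), model_387 (0.3) or model_DLE_401 (0.084). Oxidative phosphorylation genes had 59 of 76 positive fold changes and 0 over the list alone (camera adjusted p = 0.011, adjusted p = 0.88 with an estimated correlation), a call lost without model_387 (adjusted p = 0.63) or model_DLE_361 (0.56). In bile acid genes model_327 and model_387 had mean log2 CPM of 4.73 and 5.32, against 6.40 and 6.25 in model_329 and model_407 and 6.04 to 6.32 in DLE libraries. In xenobiotic metabolism genes they had 5.44 and 5.38, against 7 and 7.01 and 6.74 to 7.01. Without model_327 and model_387 together, 2 of these 7 lists remained called higher, fatty acid oxidation (adjusted p = 0.00064) and lipogenesis (0.0083), and the medians of bile acid and xenobiotic genes were 0.07 and -0.02 (adjusted p = 0.23 for both, with the test lower).

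Inflammatory and macrophage lists were lower in DLE than in model libraries, again with model_327 and model_387 holding the highest acute-phase RNA. Acute-phase protein genes fell as a list (24 of 25 with a negative fold change, 8 falling and 1 rising when adjusted over the list alone, camera adjusted p = 1.4e-07, adjusted p = 0.44 with an estimated correlation). Saa3 averaged 10.8 ± 6.64 against 1240 ± 1520 CPM (adjusted p = 0.21, and 0.031 without model_329), with 3150 CPM in model_327, 1780 in model_387, 24.2 in model_407 and 2.69 in model_329. Cytokine and chemokine genes fell with 13 of 26 over the list alone and interferon-stimulated genes with 0 of 28 (camera adjusted p = 1.4e-07 and 3.1e-07, adjusted p = 0.44 for both with an estimated correlation). The endoplasmic reticulum stress list fell with 13 of 24 over the list alone (camera adjusted p = 2.6e-06, adjusted p = 0.44 with an estimated correlation), a call lost without model_327 (adjusted p = 0.062). Kupffer cell markers fell with 11 of 14 over the list alone, and markers of recruited macrophages with 9 of 15 (camera adjusted p = 3.2e-06 and 1.4e-05, adjusted p = 0.44 for both with an estimated correlation). Adgre1, the macrophage marker F4/80, averaged 1.44 ± 0.587 against 10.2 ± 12.1 CPM, and the lysozyme gene Lyz2 20.1 ± 3.93 against 287 ± 449 CPM (adjusted p = 0.21 for both, and 0.031 for both without model_329). The library model_387 held 28.2 CPM of Adgre1 and 959 of Lyz2, against 2.15 to 6.89 and 13.2 to 108 in the other model libraries. Without it their log2 fold changes moved from -2.83 to -1.57 and from -3.84 to -1.66 (adjusted p = 0.5 for both). Neutrophil markers fell with 8 of 11 over the list alone (camera adjusted p = 0.0026, adjusted p = 0.58 with an estimated correlation) and cell cycle genes with 0 of 28 (camera adjusted p = 7.4e-05, adjusted p = 0.48 with an estimated correlation). Both lost their call without model_387 (adjusted p = 0.54 and 0.3). Erythroid markers fell with 7 of 7 over the list alone (median -1.51, camera adjusted p = 9.7e-06, adjusted p = 0.44 with an estimated correlation). Without model_327 and model_387 together, 2 of these 9 lists remained called lower, the Kupffer cell markers (median -0.92, adjusted p = 1.5e-09) and the erythroid markers (-2.08, 1.6e-23). Without model_PGZ_328 and model_DLE_361 as well, the interferon list was called higher (median 0.18, camera adjusted p = 0.023).

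The direct comparison of DLE with PGZ libraries, at doses of 200 and 20 mg/kg, called 1 gene by edgeR. Sdcbp2 was lower in DLE (1.22 ± 0.968 CPM) than in PGZ libraries (27.5 ± 11.1 CPM, log2 fold change -4.49, SE 0.59, adjusted p = 0.014, n = 4 each), and lost its call without model_PGZ_360 (adjusted p = 0.11), model_PGZ_404 (0.07) or model_DLE_401 (0.17). The next genes were Itga6, an integrin gene (2.13 ± 0.335 against 7.77 ± 3.13 CPM), and Abi3 (15.2 ± 7.2 against 58.2 ± 14.6 CPM), both with an adjusted p = 0.15. Hk2 averaged 1.6 ± 0.386 against 39.2 ± 16.9 CPM (adjusted p = 0.17) and the kinase gene Limk1 3.75 ± 1.76 against 18.2 ± 8.64 CPM (adjusted p = 0.26). These 4 genes passed without model_PGZ_328 (adjusted p = 0.044 each), as did Abi3 without model_DLE_373 (0.038). Of 15744 genes, 1516 had an unadjusted p under 0.05 and 8.43% did not overlap, against 2.86% by chance. DESeq2 called 65 genes, limma's quality weights 686, and edgeR 12 when only these groups were fitted. The count of 1 was 0 without model_PGZ_360, model_PGZ_404 or model_DLE_401, 2 without model_DLE_361, 4 without model_DLE_373 and 11 without model_PGZ_328.

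Lipid lists were lower in DLE than in PGZ libraries, with 0 members passing over all genes by edgeR. The PPAR-gamma and lipid droplet list fell with 19 of 22 negative fold changes and 3 members over the list alone (median -0.71, camera adjusted p = 3.5e-08, adjusted p = 0.28 with an estimated correlation). De novo lipogenesis fell with 0 of 25 over the list alone and adipocyte markers with 3 of 7 (camera adjusted p = 3.1e-05 and 0.0035, adjusted p = 0.28 and 0.24 with an estimated correlation). Fabp4 averaged 14.3 ± 8.92 CPM in DLE and 93 ± 36.6 CPM in PGZ libraries (adjusted p = 0.31), and Cidec 12.7 ± 10.3 and 184 ± 79.1 CPM (adjusted p = 0.41). Several lists of cells other than hepatocytes were also lower in DLE, while B cell markers (median 0.25, camera adjusted p = 1) and T and NK cell markers (-0.45, 0.29) were not called. Extracellular matrix genes fell with 25 of 28 negative fold changes, sinusoidal endothelial markers with 13 of 14, Kupffer cell markers with 14 of 14, and recruited macrophage markers with 15 of 15. Over the list alone 0, 0, 0 and 2 of them fell (camera adjusted p = 1.3e-07, 2.4e-06, 0.00017 and 6.1e-07, adjusted p = 0.39, 0.39, 0.4 and 0.28 with an estimated correlation). Cell cycle genes fell with 24 of 28 negative and 0 over the list alone (camera adjusted p = 6.4e-07, adjusted p = 0.39 with an estimated correlation). Bile acid genes were higher in DLE with 19 of 22 positive fold changes and 1 member over the list alone (camera adjusted p = 6e-04, adjusted p = 0.4 with an estimated correlation). A further 9 lists were called by camera with adjusted p between 0.0078 and 0.043 (0.28 to 0.69 with an estimated correlation), with 1 member higher over the list alone for pericentral genes, 1 lower for glycolysis and 0 for the others, and each lost its call without at least 1 library. These were higher for pericentral genes (lost without model_PGZ_404, adjusted p = 0.062, or model_DLE_361, 0.14), circadian genes (without model_DLE_378, 0.052) and female-biased genes (without model_PGZ_328, 0.14, model_DLE_361, 0.083, or model_DLE_401, 0.23). They were lower for cholangiocyte markers (without model_PGZ_360, 0.07), erythroid markers (without model_DLE_361, 0.057), cytokines (without model_PGZ_328, 0.055) and neutrophil markers (without model_PGZ_328, 0.66, or model_DLE_373, 0.14). They were also lower for glycolysis (without model_PGZ_328, 0.053, model_PGZ_360, 0.07, model_PGZ_404, 0.068, model_DLE_373, 0.059, or model_DLE_378, 0.22) and NRF2 targets (without model_PGZ_328, 0.055, model_PGZ_360, 0.16, model_DLE_373, 0.059, model_DLE_378, 0.19, or model_DLE_401, 0.084). model_PGZ_328 and model_DLE_361 held the highest Saa1 of their groups.

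Whether the treatments moved the genes altered in db/db liver back towards normal was examined over the 1429 genes called in model versus normal. With edgeR 0 of them were called in the opposite direction in PGZ and 0 in DLE, against 32 and 282 of the 2440 genes that DESeq2 called in model versus normal. Those called in the same direction, further from normal, were 1 in PGZ and 0 in DLE with edgeR and 19 and 6 with DESeq2. EdgeR called only 2 genes in PGZ versus model and 0 in DLE versus model. Its DLE count of 0 was therefore fixed in advance, and its PGZ count could not exceed 2. These comparisons had 1539 and 2249 genes at an unadjusted p under 0.05. Without model_329 the counts were 1 for PGZ and 398 for DLE, of 2909 genes called in model versus normal, and without model_DLE_378 the DLE count was 1. Of the 1429 genes, 68.1% had the opposite sign in PGZ and 82.9% in DLE. Because both contrasts share the model libraries, unchanged treatment groups simulated 50 times gave a median of 65.6% and 65.8%. These simulations drew each gene independently, so they understate how far such shares vary. With the 4 model libraries divided between the contrasts, the shares averaged 34.2% in PGZ (20.2 to 46.2%) and 58% in DLE (37.5 to 76.6%). At an unadjusted p under 0.05, 16.5% of the 1429 genes had the opposite sign in PGZ and 4.83% the same sign, against simulated medians of 6.68% and 1.45%. In DLE these shares were 41.6% and 2.1%, against 6.67% and 1.52%. The male-biased genes kept low means in the treated groups, with mean log2 CPM of 3.41 to 3.92 in PGZ and 2.78 to 4.11 in DLE libraries. Normal libraries had 7.30 to 8.29, and neither treatment called the list (camera adjusted p = 0.58 and 0.53). Slco1a1 stood at 305 ± 45.8 CPM in normal, 10.1 ± 9.67 in model, 2.32 ± 0.834 in PGZ and 4.12 ± 0.964 CPM in DLE libraries.

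The log2 fold changes of PGZ and DLE versus model had a covariance of 0.338 and a correlation of 0.63 across genes, which are not independent replicates. Simulated unchanged groups gave a median covariance of 0.128 (0.115 to 0.139) and correlation of 0.5. They drew each gene independently, while genes varied together in the data, so this range understates the spread. Other divisions of the db/db libraries gave a covariance of up to 0.452. With the model libraries divided between the treatments, the covariance averaged -0.0055 over 6 divisions (-0.332 to 0.122). At an unadjusted p under 0.05, 170 genes were higher in both and 391 lower in both, against simulated medians of 95 and 56.5 and 31.1 and 84.8 expected of independent lists. The covariance was 0.603 without model_329 and 0.522 without model_407.

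**Figure D4:**
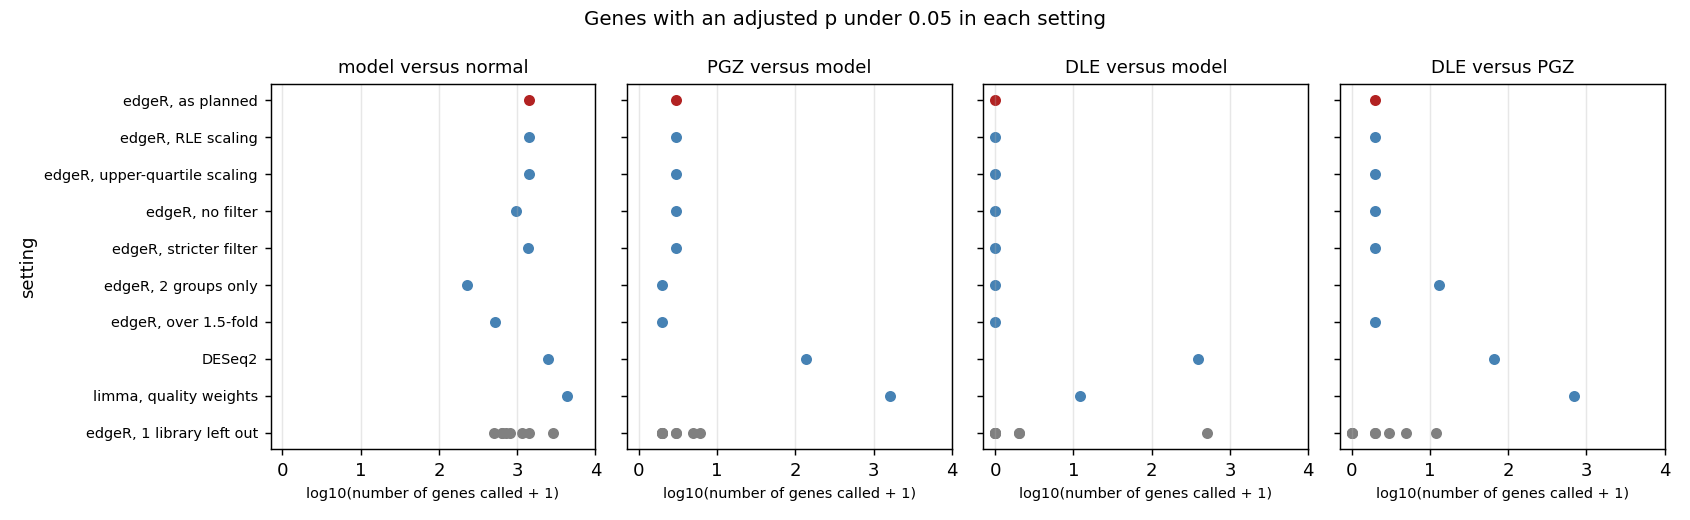
Number of genes with an adjusted p under 0.05 in each comparison (panels) under each setting (vertical axis), on a horizontal axis of log10(count + 1). Points show the count with all libraries for each tool and filter, and the counts with 1 library left out. Counts for model versus normal run from 226 to 4287, and those for DLE versus model from 0 to 511.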

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

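The explanations weighed here were all tested after the patterns had been seen, as were the counts of other divisions of the libraries except that of the covariance.

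Acute-phase RNA was far higher in model_327 and model_387 than in the other model libraries, and lists of acute-phase, cytokine, interferon and stress genes were lower in both treated groups. Lists of macrophages and neutrophils were called lower with DLE and were not called with PGZ. Neutrophils as the source of these reads are argued against in model_327, where the mean of the neutrophil markers lay 5.54 log2 units below that of model_387 while Saa1 was higher, but cannot be told apart in model_387 (S100a8 and S100a9 at 0.054 of Saa1 and Saa2), since those markers were highest there (6.70) and also in model_PGZ_328 (4.57) and model_DLE_361 (1.99) within their groups. Library size is argued against as well, because the lower of the pair held 7.49 times the Saa1 CPM of the next model library while model read totals differed 1.4-fold. So is a swap with the normal group, since both lay at least 3.57 log2 units below every normal library in male-biased genes. Both lay at no more than 0.023 of the lowest PGZ library in Sdcbp2. That gene stood out in these same data because every PGZ library lay above every model library, so it cannot decide on a swap with the PGZ group. A swap with the DLE group was not examined. Without model_327 and model_387, 2 of 9 lists remained called lower with DLE and 1 of 5 with PGZ. A further list lower with PGZ, of pericentral genes, remained so too. The acute-phase median moved from -1.59 to 0.47 with DLE and from -1.81 to 0.26 with PGZ. Most of the calls thus depended on this pair. It was chosen for its high acute-phase RNA, so a loss in such lists was fixed in advance, and fewer model libraries remained. The exclusion therefore cannot decide whether the levels of the pair account for the lower lists. No biological explanation was tested for the difference between animals of the model group.

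Male-biased liver genes were lower and female-biased ones higher in model than in normal libraries. Female animals in the model group are argued against by at least 1083 reads of the Y-linked Ddx3y and at most 8 of Xist in each model library. Reads shared between near-identical gene copies are argued against for male-biased genes by the 8 members outside multigene families, 7 of them called lower, with a median log2 change of -3.40, but cannot be told apart from a change for female-biased genes, where 5 of 11 such members were called higher and 1 lower (median 2.06, against 6.24 and 11 of 15 higher within families). Sequence linked to the Lepr mutation is argued against only as acting on the genes near it. Of 34 called members 1 (2.94%) lay within 20 Mb of Lepr, and the members were spread over 12 chromosomes in all. The positions of the genes cannot decide on linked sequence that acts on genes elsewhere. A hypothesis that remains is that biology of the db/db animals may underlie the lower male-biased genes, but genotype and diabetes differ together between these groups, the strain background of the db/db mice was not given in the sources used here, and these were not tested apart.

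In 348 groups of 4 libraries examined, 32 libraries lay far from the other 3 of their group, where chance marks about 1 in 20 groups, or 17.4. Of these, 7 were in normal_376 and 6 in model_387. In normal_376 they were high CPM of Acaca (104), Pnpla2 (119), Tnfaip3 (5.53), Selenbp2 (4400) and Mpo (0.0489, from a single read) and low CPM of Cyp7b1 (122) and Hsd3b5 (85.1). In model_387 they were high Mpo (244), Cdc42ep2 (16.6) and Moxd1 (1.3, against 0 in the others) and low Fabp4 (9.15), Pex11a (67.6) and Sdcbp2 (0.166). The library model_PGZ_328 was low in Cd36 (128 against at least 232 CPM in the others) and Cidec (68.9 against at least 197) and held 2.26 CPM of Moxd1 against 0. The library model_DLE_361 held 8.5 CPM of Cyp2b13 against at least 226 in the others, 7.92 of Moxd1 against 0 and 4.98 of Mpo. High values were 3010 CPM of Cyp4a14 in model_DLE_401, 941 of Fbp1 in model_327, 222 of Osgin1 in model_329, 7.88 of Lepr in model_PGZ_404, 11.1 of Tnfaip3 in model_PGZ_360, 2.4 of Itga6 in normal_409, and 7.64 of Cfd and 84.8 of Lbp in normal_349. Values near the floor were 0.108 CPM of Cidea in normal_349, 0.447 of Mup-ps7 in model_DLE_373 and 0.0403 of Serpina9 in model_PGZ_360. Lgals3 was low in normal_409 at 0.96 CPM against at least 1.96, and S100a9 in normal_349 at 0.323 CPM against at least 0.581.

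Each comparison was repeated for every division of its 8 libraries into groups of 4, 35 in all. For genes in model versus normal, chance is argued against, with 1429 called, at most 2 in any other division and 1 division as large. That is a share of 0.029, the smallest that 35 divisions can give. Chance cannot be excluded for the lists of that comparison, with 17 called, up to 21 in others and 18 as large, nor with an estimated correlation, where 1 was called, up to 1 in others and 4 as large. Nor can it for PGZ versus model, with 2 genes called against up to 6 (2 as large) and 16 lists against up to 23 (23 as large). The division calling 6 genes set model_327, model_PGZ_360, model_PGZ_404 and model_PGZ_408 against the rest. It differs from the real one only by the exchange of model_327 and model_PGZ_328, so it keeps most of the PGZ contrast. The division counts concern the number of genes called, not Sdcbp2 itself. With an estimated correlation 2 lists were called in PGZ versus model and 0 in every other division (1 as large). This is again the smallest share possible, but several counts were tested in this way without adjustment, so chance cannot be excluded. In DLE versus model 0 genes were called, and the division that set model_327, model_387, model_407 and model_DLE_361 against the rest called 1477. That division differs from the real one only by the exchange of model_329 and model_DLE_361, so it keeps most of the treatment contrast. It was also the largest of the 35, so it cannot separate the treatment from another structure of the libraries. Saa1 followed this division, with 1360 to 27800 CPM in the libraries named and 54.9 to 221 CPM in the rest. In that comparison 16 lists were called against up to 25 (24 as large), for which chance cannot be excluded. A count of 0 cannot be tested in this way, since all 35 divisions give as many. This holds for the 0 genes called in DLE versus model, the 0 moved back by PGZ (up to 2 in others) and by DLE (up to 91), and the 0 lists called with an estimated correlation in DLE versus model (up to 2) and in DLE versus PGZ (up to 1). Chance can also not be excluded for DLE versus PGZ, with 1 gene called against up to 54 (3 as large) and 18 lists against up to 20 (4 as large). The division calling 54 set model_PGZ_328, model_DLE_361, model_DLE_378 and model_DLE_401 against the rest. It too keeps most of the contrast, since only model_PGZ_328 and model_DLE_373 were exchanged. The covariance of the treatment effects was 0.338, and 7 of 60 divisions of the db/db libraries gave as much, up to 0.452, so chance cannot be excluded.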

How the results depend on the processing

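Leaving out model_327 and model_387, with or without model_PGZ_328 and model_DLE_361, was chosen after the data were seen. No paired analysis was possible because the number in the labels differs in every library. Alternatives for comparisons with white tea extract were not run. At this depth 3 reads over a group stood for 0.041 CPM in normal and 0.035 CPM in model libraries, below which no difference is detectable. RLE and upper-quartile scaling, under which the median difference of all genes (log2) stayed within 0.05 of 0, kept every count of genes within 1.5 times, as did the stricter filter. Upper-quartile scaling turned Lepr in PGZ versus model to 0.01 (adjusted p = 1). In model versus normal the count of 1429 became 952 without a filter, 226 with only these groups fitted (110 higher and 116 lower, against 973 and 456), 524 for a fold over 1.5, 2440 with DESeq2 (1595 and 845) and 4287 with voom (2243 and 2044). In PGZ versus model the 2 genes became 1 with only these groups fitted, 1 for a fold over 1.5, 135 with DESeq2 and 1598 with voom, where Tnfaip3 turned to 0.01 (adjusted p = 0.99). In DLE versus model DESeq2 called 386 and voom 11 in place of 0, and in DLE versus PGZ 12 were called with only these groups fitted, 65 with DESeq2 and 686 with voom in place of 1. Genes moved back were 32 for PGZ and 282 for DLE with DESeq2, beside 19 and 6 moved further from normal. The cause was not tested. In the simulated data DESeq2 made 21% false calls in model versus normal, against 3.8% with edgeR and 3.8% with voom. Those data used edgeR's own dispersions, alike in all groups, with each gene independent. EdgeR and voom had equal false shares there but called 1429 and 4287 genes in the real data. The simulation therefore cannot decide whether the further calls of DESeq2 are false.

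With an estimated correlation camera called 1 list in model versus normal, 2 in PGZ versus model, 0 in DLE versus model and 0 in DLE versus PGZ. Fry, which tests whether the genes of a list move one way without comparing them with other genes, called 8, 3, 0 and 0, and for change in either direction 23 in model versus normal, 6 in PGZ versus model, 0 in DLE versus model and 2 in DLE versus PGZ. For camera only the correlation used differed between the settings, so its fewer calls came from that. The cause of the different counts from fry was not tested. With the model libraries divided between the treatments the covariance of their effects averaged -0.006 over 6 divisions in place of 0.338. The divisions ranged from -0.332 to 0.122, so its sign stays open.

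Without model_327 and model_387 the counts were 438 in model versus normal, 4 in PGZ versus model, 1 in DLE versus model and 27 in DLE versus PGZ, with 9 lists in DLE versus model, 19 in model versus normal (9 of the 17 called with all libraries) and 1 gene moved back and 1 moved further by PGZ. Log2 values or directions of list tests that reversed there were 0.46 for Cyp7a1 and -0.03 for ribosomal proteins in model versus normal. In PGZ versus model they were 0.07 for Lbp, 0.76 for Tlr2, 0.54 for Tnfaip3, 0.16 for Creld2, 0.20 for Lepr, -0.30 for xenobiotic metabolism (median -0.01 with all libraries, where only the test was higher), 0.26 for acute-phase, 0.59 for cytokine and 0.14 for stress genes. In DLE versus model they were 0.18 for Creld2, 0.07 for bile acid genes (where the test was lower), -0.02 for xenobiotic metabolism, 0.47 for acute-phase genes, -0.16 for female-biased genes and 1.34 for neutrophil markers. Of these, the xenobiotic (adjusted p = 2.6e-05) and cytokine lists (0.01) of PGZ versus model passed. Without model_PGZ_328 and model_DLE_361 as well, the counts were 726, 216, 2 and 497, with 22 lists in model versus normal (12 of the 17), 20 genes moved back and 14 moved further by PGZ and a covariance of 0.237. Reversed there were Cyp7a1 (0.47) and ribosomal proteins (-0.03) in model versus normal. In PGZ versus model Tlr2 (0.71), Tnfaip3 (0.56), Creld2 (0.01), Lepr (0.25), xenobiotic metabolism (-0.37, by its test alone), cytokines (0.62) and stress genes (0.08) reversed. In DLE versus model Isg15 (0.02), Creld2 (0.01), bile acid genes (0.01, test lower), xenobiotic metabolism (-0.08), cytokines (-0.04, test higher), interferon-stimulated genes (0.18), female-biased genes (-0.29) and oxidative phosphorylation (-0.06) reversed. Of these, xenobiotic metabolism with PGZ (adjusted p = 0.00078) and the interferon list with DLE (0.023) passed. Beyond the smaller number of libraries, the cause was not tested.

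With 1 library left out the counts of genes ranged from 505 to 2909 in model versus normal, 1 to 5 in PGZ versus model, 0 to 511 in DLE versus model and 0 to 11 in DLE versus PGZ. Lists ranged from 17 to 19, 12 to 17, 12 to 21 and 14 to 20, genes moved back from 0 to 1 for PGZ and 0 to 398 for DLE, and the covariance from 0.253 to 0.603. Lepr in PGZ versus model ranged from -0.33 without model_PGZ_404 to 0.13 without model_327, and was 0.01 without model_PGZ_408, and the test of xenobiotic metabolism turned lower without model_387 (median -0.09, against -0.01). Of 1568 values of single genes in these fits 1306 kept their direction and side of the threshold, 219 lost and 41 gained a call, and of 536 of single lists 479 kept it and 56 lost the call.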

Other observations

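Some of the tests in this part were chosen only after the result was seen, namely that of antigen-presenting cells; those of haplotypes and of gene copies were set beforehand.

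Genes of a liver zone and of the clock differed between model and normal libraries in ways their lists as a whole did not. Of 15 pericentral hepatocyte genes 3 rose and 12 were not called, with 3 rising when adjusted over the list alone (camera adjusted p = 0.39). Rhbg, an ammonium transporter gene, rose from 0.977 ± 0.213 to 5.01 ± 1.38 CPM (log2 fold change 2.35, SE 0.43, edgeR adjusted p = 0.005, n = 4 each), and Oat, the ornithine aminotransferase gene, from 482 ± 115 to 1880 ± 858 CPM (adjusted p = 0.016). Oat lost its call without normal_376 (adjusted p = 0.051) or normal_409 (0.052). Of 20 circadian clock genes 1 rose, 2 fell and 17 were not called (camera adjusted p = 0.25), and the clock repressor gene Nr1d1 fell from 301 ± 50.9 to 91 ± 50.5 CPM (adjusted p = 0.019, and 0.057 without normal_409). The other called members were Bhlhe41, which fell, and Cry1, which rose. Both lost their call without any 1 of the 4 normal libraries (adjusted p = 0.058 to 0.076 and 0.065 to 0.12).

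Nnt, a mitochondrial transhydrogenase gene that carries a deletion in C57BL/6J mice, had 32.3 to 43.2 CPM in normal libraries, 92.8, 60.6, 41.8 and 72.2 in model_327, model_329, model_387 and model_407, 75.2 to 96.5 with PGZ and 46.6 to 73.2 with DLE. Its call in model versus normal (log2 fold change 0.76, adjusted p = 0.04) was lost without any 1 of the 4 normal libraries and without model_327 or model_407 (adjusted p = 0.075 to 0.11), and held only without model_329 or model_387.

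RNA of the major histocompatibility region (chromosome 17, GRCm38) fell into separate levels that crossed the groups. Rps18, a ribosomal protein gene (33951999 to 33956001), had 20.6 to 42 CPM in 10 libraries, the 4 normal ones among them, 144 to 156 CPM in model_329, model_PGZ_360, model_PGZ_404, model_DLE_373 and model_DLE_378, and 268 CPM in model_407. H2-K1 (33996017 to 34000347) had 1770 CPM in model_407, and the pseudogene H2-Ea-ps (34341959 to 34344645) had 3 reads there against at least 55 in each other library. C57BL/6J mice carry a deletion that stops transcription of H2-Ea, yet the normal libraries, labelled C57BL/6J, held 55 to 118 of these reads, so their origin is uncertain and was not tested.

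Fewer antigen-presenting cells in model_407 are argued against, since its reads of H2-Eb1 at the lowest ratio of the other 15 libraries (0.24) would give 542 reads of H2-Ea-ps, not 3. Different haplotypes of the region among the animals may underlie the levels, but of the 10 genes that followed Rps18 most closely 3 lay between 30 and 40 Mb of the chromosome, where 1.4% of the genes ranked lie, fewer than the 5 set beforehand as needed and more than the 1 that would have argued against it. For reads that move between Rps18 and its copies Rps18-ps3 and Gm10260, the test set beforehand could not decide. The sum of the copies differed 2.01-fold between libraries (183 to 368 CPM), just over its bound of 2 and below that of 4. Both extremes, normal_376 and model_DLE_361, were libraries with low Rps18 (42 and 33.5 CPM). The sum was 224 to 262 CPM in the libraries of the middle Rps18 level and 269 CPM in model_407, where Rps18 was highest. Gm10260 stood at 137 to 312 CPM at the low level, 75.5 to 98.9 at the middle level and 0.553 in model_407. These values argue against a change in the summed RNA of the copies as the source of the 3 levels. Genotypes at this region were not tested, and the strain background of the db/db mice was not given in the sources used here.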
